A study of Mus musculus with 22 samples.

How the data were processed

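RNA of mouse cells was sequenced in 22 libraries from 3 experiments. Bone marrow myeloid cells of wild-type (WT) mice and of mice with a knockout (KO) of VISTA, the checkpoint protein encoded by Vsir, were cultured in normoxia until day 4 or in hypoxia for 24 hours, with 4 libraries per genotype in each condition. A further experiment holds MC38 tumor samples taken at day 7, with 3 libraries per genotype. MC38 is a mouse colon carcinoma line, and the labels do not say whether cells were purified from the tumors. The names of the deposited count tables, the tumor table included, speak of MDSC (myeloid-derived suppressor cells). The strain background is given as C57BL/6N for the KO and WT samples alike. Groups and replicate numbers were taken from the sample titles, and the oxygen condition of a culture column was taken from the table it stands in. The KO columns of the culture tables carry a code that does not spell out the genotype. They were read as KO by elimination, since the other columns are named WT, and Vsir levels were not used for this. Libraries were made with a Takara SMART-Seq kit, per the labels' protocols. The labels state that the normoxia cultures are independent biological replicates, and no such statement is given for the other experiments. Within each group, the counts of any pair of libraries differed by more than counting error (chi-square per degree of freedom of at least 4.91), so no library was a copy of another.

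The authors deposited a table of raw counts per Ensembl gene for each experiment, made with Subread and featureCounts against GRCm38.p6, per the submitters' processing notes, which give no versions. The values checked as whole numbers, and each gene listed has at least 2 counts over its table, so genes with fewer were left out before deposit. The authors also deposited a table of normalized signal for each experiment, made with DESeq2 per the submitters' processing notes. Each of its columns equals the raw counts times 1 factor per library, within a relative tolerance of 1e-09. The counts were used for all main results, and the normalized values were used for 1 alternative. The strand setting of the counting is not stated, so reads of a gene and of an antisense neighbour cannot be told apart here.

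Gene symbols and positions came from GENCODE M21 (GRCm38). It held 23860 of the 23912 identifiers of the normoxia table, 33161 of 33265 in hypoxia and 24199 of 24251 in the tumor table. Total counts per library ranged from 23409142 to 23722932 in normoxia, from 30839108 to 31385825 in hypoxia and from 19119985 to 31716200 in the tumor experiment. The 10 genes with most counts took 8.22% to 12% of a library.

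Each experiment was fitted alone in R 4.3.3 with edgeR 4.0.16 (filterByExpr with the groups, TMM scaling, quasi-likelihood test with robust dispersions, Benjamini-Hochberg adjustment, threshold 0.05). This left 13950 tested genes in normoxia, 15018 in hypoxia and 14370 in the tumor experiment. The difference between the KO effects in hypoxia and normoxia was tested as an interaction over the 16 culture libraries, and hypoxia WT was compared with normoxia WT over 8 libraries. In both, oxygen is confounded with the length of the culture and with the table a library stands in. Only a shift common to both genotypes cancels in the interaction. Levels are CPM, counts scaled to the TMM-adjusted library size, given as mean ± SD. They differ slightly between comparisons that scale different libraries together. Fold changes are log2 values of KO against WT with their standard errors (SE). The level of Vsir was also compared by an exact two-sided permutation test of log2(CPM + 1).

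Gene lists were fixed with the rest of the design before the data were examined. They cover polyamine, IL-6 and STAT3, suppressive myeloid, glycolysis, HIF target, respiratory chain, citric acid cycle, amino acid, interferon, cytokine, granulocyte, and dendritic cell and MHC class II genes. Others hold markers of mast cells and basophils, eosinophils, erythroid cells, and T and NK cells, or immediate early genes. Lists with at least 5 measured members were tested with camera (limma 3.58.1, inter-gene correlation 0.01) on log2 CPM with a prior count of 2. Camera was repeated with a correlation estimated per list, and fry was run beside it. Called means an edgeR adjusted p under 0.05 for a gene and a camera adjusted p under 0.05 for a list.

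Named genes were also fixed by rule. They are Vsir, and the 6 largest rises and 6 largest falls per KO comparison among called genes with a mean log2 CPM of at least 3 and no overlap between the genotypes. Predicted and clone-named genes were passed over. The difference of effects and the oxygen comparison take 5 per direction. Up to 4 members with the smallest p are named from each list described. A set of 14 genes was named in each KO comparison where measured (Arg1, Nos2, Odc1, Stat3, Socs3, S100a8, S100a9, Hif1a, Slc2a1, Cpt1a, Il1b, Cd274, Ly6g and Ly6c2), and Cdh23, Psap and Nnt served as checks.

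The scripts were tested on simulated counts drawn from the means and library sizes of the real libraries, with known changes in a seeded set of genes. These genes had a mean log2 CPM of at least 3, so recovery at lower levels was not tested. At 1.5-fold, edgeR recovered 74.2% of the changed genes of the normoxia design, 95.5% in hypoxia, 89.1% in the tumor design, 42.4% for the difference of effects and 95.5% for the oxygen comparison. At 2-fold the shares were 96.9%, 100%, 100%, 95.4% and 98.5%. Between 3.21% and 7.55% of the calls were false. Camera with either correlation and fry called the list that had been raised in each design and 0 of 20 unchanged lists. The simulated genes were drawn independently of each other. This does not show how often the list tests err where genes are correlated.

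Alternatives were DESeq2 1.42.0, limma-voom, DESeq2's size factors in edgeR, library size alone, no filter, a mean count of at least 10, a fold threshold of 1.2, the replicate number as a block, the deposited normalized values with limma, and leaving out each library in turn. Alternatives that leave out certain chromosome windows or a pair of normoxia libraries were added after the data had been seen, and so were the list tests for the difference of effects. Windows of 5 Mb were scanned for an excess of called genes with a hypergeometric test and a Bonferroni bound. Lists with fewer than 5 measured members were not tested.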

Results

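RNA was measured in 22 libraries. Bone marrow myeloid cultures gave 4 WT and 4 KO libraries in normoxia (day 4) and 4 and 4 in hypoxia (24 hours), and MC38 tumor samples (day 7) gave 3 and 3. Libraries held 23409142 to 23722932 counts in normoxia and 30839108 to 31385825 in hypoxia. In the tumor experiment the WT libraries held 27452024 to 31716200 counts and the KO libraries 19119985 to 23089943. The comparisons address what loss of VISTA changes in myeloid suppressor cells, with the title of the study naming metabolism, STAT3 and polyamines.

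Vsir (ENSMUSG00000020101, chromosome 10, 60346851 to 60372684, GRCm38) was lower in each KO library than in any WT library of its experiment. Its level was 713 ± 97.5 CPM in WT and 177 ± 47.6 CPM in KO normoxia cultures (SD, n = 4 each). Hypoxia cultures had 546 ± 44.3 and 147 ± 23.2 CPM (n = 4 each), and tumor samples had 459 ± 28.3 and 118 ± 8.36 CPM (n = 3 each). KO libraries thus kept 24.8%, 26.9% and 25.8% of the WT level. The exact two-sided permutation test gave p = 0.0286 in each culture experiment and p = 0.1 in the tumor experiment, in each case the smallest p the design allows. The log2 fold changes were -2.01, -1.89 and -1.95. Vsir lies inside Cdh23, a cadherin gene on the other strand (chromosome 10, 60302748 to 60696490), and no exons of the 2 genes overlap. Cdh23 was higher in KO in all 3 experiments (log2 fold change 2.13, 2.34 and 1.58). With 0 Cdh23 exons inside the span of Vsir, reads within Vsir would not count for Cdh23 where exons are counted. The strand of the reads in Cdh23 exons is not known. Psap, a neighbour, did not pass the test in any of the 3 (log2 fold change -0.11, -0.27 and -0.06). Nnt, part of which is deleted in C57BL/6J mice, was at 0.443 and 0.534 CPM in WT and KO in normoxia and at 0.553 and 0.411 CPM in hypoxia, with no call, and was not measured in tumor. Of the genes known to differ between C57BL/6 substrains, Nlrp12 rose and Entpd4 and Entpd4b fell in normoxia (1.21, -0.61 and -0.58), Nlrp12 and Wdfy1 rose in hypoxia (1.09 and 0.32) and Wdfy1 fell in tumor (-0.38). The predicted genes Gm16867 and Gm27177, on chromosome 14 from 69363504 to 69683286, were chosen after their values were seen. They rose in normoxia (7 and 6.93), hypoxia (5.15 and 5.17) and tumor (7.18 and 8.35). Whether KO and WT animals share the same background was not tested.

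**Figure D1:**
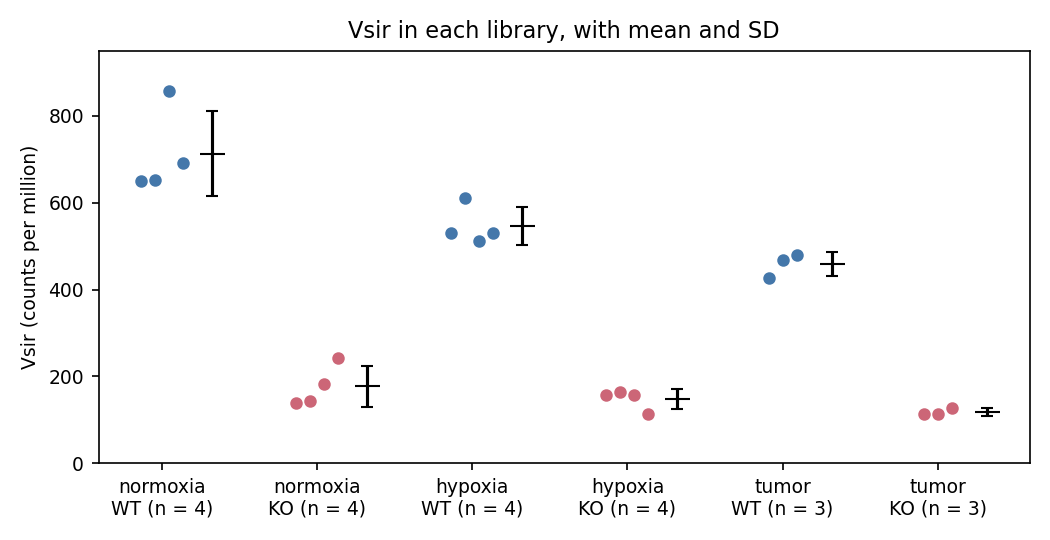
Vsir in CPM (y axis) for each library (points) by experiment and genotype (x axis), with the mean and SD of each group as a bar beside its points. The KO means are 177, 147 and 118 CPM and the WT means 713, 546 and 459 CPM.

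In normoxia cultures without VISTA, genes of neutrophil granules, mast cells, eosinophils and antigen presentation were higher, and more genes of the amino acid and cytokine lists were lower than higher. These lists passed at a fixed correlation and not with an estimated one. Genes of the mitochondrial genome, whose share RNA quality can move, were higher with them. Arg1, the arginase that removes arginine, had 26.2 ± 18.2 CPM in WT and 3.75 ± 3.22 CPM in KO cultures (SD, n = 4 each, log2 fold change -2.81 ± 0.71 SE). Ly6g, a neutrophil surface marker, rose from 72.1 ± 20.8 to 156 ± 54.6 CPM. The MHC class II genes H2-Aa and H2-Eb1 rose from 10.2 ± 5.66 to 51.5 ± 23.1 CPM and from 6.64 ± 4.08 to 33.5 ± 16.3 CPM. Il1a, which encodes an inflammatory cytokine, fell from 6 ± 1.11 to 1.01 ± 0.339 CPM.

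The largest rises under the rule were Grap (log2 fold change 4.11), the immunoglobulin genes Igha (4.08) and Igkc (3.92), Retnlg (2.38), H2-Eb1 (2.34) and H2-Aa (2.33). The largest falls were the interferon-inducible Ifi204 (-2.78), Vsir, Acod1 (-1.67), which makes itaconate, Spp1 (-1.59), the arginine transporter gene Slc7a2 (-1.41) and the cyclin gene Ccnd2 (-1.40). Igha, Igkc and Ifi204 belong to families of similar genes, so how their reads were assigned is uncertain.

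Granulocyte genes rose in normoxia: 11 of 24 measured members were called higher and 0 lower, or 16 and 0 when adjusted over the list alone. Csf3r, the receptor of G-CSF, rose from 185 ± 51.6 to 392 ± 124 CPM, Cd177 had a log2 fold change of 0.72, Camp 0.80 and Cebpe 0.61. S100a8 and S100a9 did not pass (log2 fold change 0.40 and 0.46, adjusted p = 0.102 and 0.0882 in edgeR). The list had a camera adjusted p = 6.44e-06, and adjusted p = 0.371 with an estimated correlation. All 7 measured mast cell and basophil genes rose, also adjusted over the list alone, with Hdc, the histidine decarboxylase gene, at 23 ± 4.2 CPM in WT and 51.8 ± 10.2 CPM in KO. Prss34, Gata2 and Kit had log2 fold changes of 1.07, 1.17 and 0.72. With camera the adjusted p was 5.92e-07, and adjusted p = 0.244 with an estimated correlation. Of 7 eosinophil genes, 4 rose (5 adjusted over the list alone): Prg2 (1.40), Prg3 (2.16), Epx (1.5) and Ear1 (1.52). The eosinophil list had a camera adjusted p = 0.00107, and adjusted p = 0.371 with an estimated correlation.

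Among dendritic cell and MHC class II genes, 6 of 17 rose and 1 fell (7 and 1 adjusted over the list alone), with Ciita, the class II transactivator, at a log2 fold change of 2.50 and H2-Ab1 at 2.07. In the camera test the adjusted p was 0.000739, and adjusted p = 0.371 with an estimated correlation. Interferon-stimulated genes were called higher in 6 of 29 cases and lower in 0 (15 and 1 adjusted over the list alone). Cmpk2 (1.21), Oas2 (0.88), Oas3 (0.55) and Rsad2 (0.91) were among them. The camera adjusted p was 5.92e-07, and adjusted p = 0.371 with an estimated correlation.

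Amino acid genes fell in normoxia, with 6 of 20 called lower and 0 higher (11 and 0 adjusted over the list alone). Ass1, which makes arginine from citrulline, fell from 277 ± 20.2 to 136 ± 34 CPM, while Asns and Slc7a11 had log2 fold changes of -0.77 and -0.65. Tested with camera, the list had adjusted p = 7.75e-05, and adjusted p = 0.371 with an estimated correlation. Of 21 polyamine genes, 3 fell and 1 rose (5 and 1 adjusted over the list alone). Arg1, the spermine synthase gene Sms (-0.68) and Slc3a2 (-0.37) fell and Arg2 (0.73) rose, whereas Odc1, the rate-limiting ornithine decarboxylase, had a log2 fold change of -0.67 with adjusted p = 0.105 in edgeR. The polyamine list did not pass (camera adjusted p = 0.0688).

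HIF targets, genes raised in low oxygen, fell in 7 of 22 cases and rose in 1 (12 and 1 adjusted over the list alone). Hilpda (-1.04), Egln3 (-0.70), Pdk1 (-0.65) and Slc2a1 (-0.52), the main glucose transporter gene, fell and Pfkfb4 (0.68) rose. Camera gave adjusted p = 0.00304, and adjusted p = 0.371 with an estimated correlation. Cytokine genes fell in 9 of 22 cases and rose in 2 (10 and 2 adjusted over the list alone), with Il1b at -0.85, Csf1 at -0.82 and Ccl4 at -1.05. Their camera adjusted p was 0.00448, and adjusted p = 0.371 with an estimated correlation. In the IL-6 and STAT3 list, 7 of 26 genes rose and 2 fell (9 and 2 adjusted over the list alone). Socs3, a feedback inhibitor of STAT3, rose (0.43), as did Cebpd (0.62) and Csf3r (1.08), while Icam1 (-0.46) and Hif1a (-0.43) fell. Stat3 itself did not pass (0.30, adjusted p = 0.108 in edgeR), nor did Nos2 (-0.99, adjusted p = 0.258), Cpt1a (0.07, adjusted p = 0.663) or Ly6c2 (0.28, adjusted p = 0.0637), and Cd274, which encodes PD-L1, fell (-0.39). That list had a camera adjusted p = 0.0368, adjusted p = 0.371 with an estimated correlation, and adjusted p up to 0.0797 when 1 library was left out. All 13 genes of the mitochondrial genome lay above 0 (median 0.371), and 3 were called higher (13 adjusted over the list alone, 0 without WT replicate 1, 2 or 4 or KO replicate 1, 3 or 4). Camera gave adjusted p = 4.21e-05 there, and adjusted p = 0.371 with an estimated correlation.

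By edgeR, 995 of 13950 genes rose and 582 fell in normoxia, 1577 in all. With library size alone the balance turned, and 726 rose and 951 fell. Without WT replicate 1, the called members were 3 of the granulocyte list (11 with all libraries), 3 of the interferon list (6), 4 HIF targets (8), 5 cytokine genes (11), 2 of the IL-6 and STAT3 list (9), 4 amino acid genes (6) and 2 eosinophil genes (4). Leaving out other libraries raised some of these counts. Without WT replicate 3, 12 interferon genes and 11 dendritic cell and MHC class II genes (7 with all libraries) were called. Without KO replicate 2, 12 interferon and 10 amino acid genes were called. The genotypes did not overlap for 20% of the tested genes, where chance gives 2.86%. The count fell to 469, 723 and 632 without WT replicate 1, 2 or 4 and to 696 without KO replicate 3, was 2881 without KO replicate 4 and WT replicate 3, which stood apart in a principal component plot, and was 2388 with DESeq2 and 416 with a fold threshold of 1.2. Of the 52 called genes named here, 16 lost their call when 1 library was left out, among them Arg1, for which the edgeR adjusted p was 0.0387 with all libraries and 0.155 without KO replicate 4.

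**Figure D2:**
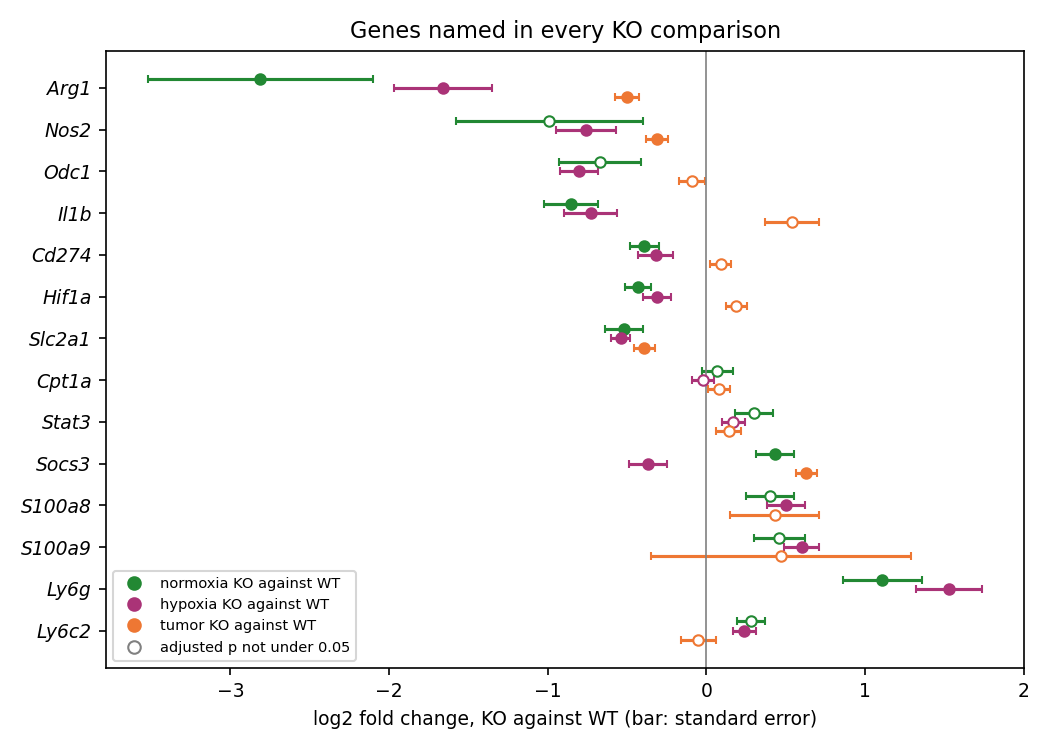
Log2 fold change of KO against WT (x axis, bars are standard errors) for the genes named in each comparison (y axis), by experiment (colour), with open points where the edgeR adjusted p is not under 0.05. Arg1 is at -2.81, -1.66 and -0.50 and Slc2a1 at -0.52, -0.54 and -0.39 in normoxia, hypoxia and tumor, while Ly6g has no tumor value because its counts did not pass the filter.

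In hypoxia cultures without VISTA, neutrophil, eosinophil and mast cell genes were higher, and genes of the respiratory chain, the citric acid cycle and amino acid metabolism and transport were lower. With an estimated correlation 0 of these lists passed. Ngp, a neutrophil granule protein, rose from 12100 ± 1600 to 28400 ± 3380 CPM and Ly6g from 24.5 ± 2.8 to 70.6 ± 24.2 CPM (SD, n = 4 each). Arg1 fell from 154 ± 35.8 to 49 ± 22.9 CPM (log2 fold change -1.66 ± 0.31 SE) and Odc1 from 110 ± 16.7 to 63 ± 7.84 CPM (-0.80 ± 0.12 SE). The alpha and beta globin genes Hba-a1 and Hbb-bs fell from 24.4 ± 11.9 to 3.98 ± 1.28 CPM and from 21.8 ± 11.4 to 2.67 ± 0.776 CPM.

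The largest rises were Mid1 (log2 fold change 4.35), Grap (3.45), Igha (3.31), Igkc (3.18), Cdh23 (2.34) and Fcrlb (1.98). The largest falls were Hbb-bs (-3.03), Hba-a2 (-2.65), Hba-a1 (-2.62), Olfml2b (-2.43), Vsir and the myelin protein gene Pmp22 (-1.88). Globin genes are near-identical copies, and their separate values are uncertain. Mid1-ps1 on chromosome Y rose with Mid1 (4.38), and how reads were divided between these is uncertain too. Of 6 erythroid genes, 4 fell and 0 rose, or 4 and 1 adjusted over the list alone, with Hbb-bt at -2.81, but the list did not pass (camera adjusted p = 0.0772).

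Respiratory chain genes encoded in the nucleus fell in 62 of 76 cases and rose in 0 (67 and 0 adjusted over the list alone), with a median log2 fold change of -0.355. Examples are the ATP synthase gene Atp5g1 (-0.85), Uqcr10 (-0.50) and the succinate dehydrogenase genes Sdhc (-0.56) and Sdhb (-0.47), which are also on the citric acid cycle list. With camera the adjusted p was 2.1e-14, and adjusted p = 0.535 with an estimated correlation. Of 23 citric acid cycle genes, 16 fell and 0 rose, the same numbers adjusted over the list alone, with Idh2 at -0.65 and Suclg2 at -0.63. The camera adjusted p was 1.98e-05, and adjusted p = 0.535 with an estimated correlation. Amino acid genes fell in 13 of 20 cases and rose in 0 (14 and 0 adjusted over the list alone). Ass1 (-1.37), the serine synthesis genes Phgdh (-0.91) and Psat1 (-0.74), and Got1 (-0.46) were among them. In the camera test the adjusted p was 3.27e-05, and adjusted p = 0.389 with an estimated correlation. In the polyamine list, 8 of 21 genes fell and 2 rose (9 and 3 adjusted over the list alone), including Odc1, Arg1, Eif5a (-0.57), whose protein carries hypusine, and Slc3a2 (-0.27). The list did not pass (camera adjusted p = 0.0639).

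Granulocyte genes rose in 17 of 24 cases and fell in 0 (19 and 0 adjusted over the list alone), among them Ltf (1.17), Lcn2 (0.85) and Cd177 (0.92). Tested with camera, the list had adjusted p = 2.64e-08, and adjusted p = 0.389 with an estimated correlation. All 9 eosinophil genes rose, also adjusted over the list alone, with Ear6 at 63.7 ± 9.5 CPM in WT and 147 ± 23.6 CPM in KO and Siglecf, Ear2 and Ccr3 at log2 fold changes of 1.01, 1.12 and 1.85. The Ear genes are close paralogs. With camera the adjusted p was 3.48e-06, and adjusted p = 0.389 with an estimated correlation. Of 10 mast cell and basophil genes, 9 rose and 0 fell, the same adjusted over the list alone, with Cpa3, a mast cell protease, at 0.86, Kit at 0.82, Gata1 at 0.96 and Fcer1a at 1.18. Camera gave adjusted p = 0.000327, and adjusted p = 0.535 with an estimated correlation.

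Interferon-stimulated genes rose in 10 of 26 cases and fell in 1, the same adjusted over the list alone. Cmpk2 (1.63) and Oas3 (0.83) rose and Bst2 (-0.72) fell. The list had a camera adjusted p = 0.00292, and adjusted p = 0.535 with an estimated correlation. Suppressive myeloid genes went both ways, with 7 of 24 higher and 4 lower (8 and 4 adjusted over the list alone, camera adjusted p = 0.251). The NADPH oxidase genes Cybb (0.63), Ncf1 (0.45) and Ncf4 (0.39) and the calprotectin genes S100a8 (0.50) and S100a9 (0.60) rose, while Arg1, Nos2 (-0.76), Il1b (-0.73) and Cd274 (-0.32) fell. In the cytokine list, 9 of 24 genes fell and 2 rose (9 and 3 adjusted over the list alone, camera adjusted p = 0.264), with Il1a at -1.68, Cxcl1 at -1.46 and Ccl17 at -1, and Il27 at 1.07. HIF targets did not pass in hypoxia, with 4 of 22 higher and 3 lower, the same adjusted over the list alone (camera adjusted p = 0.651). Slc2a1 fell (-0.54) and Mxi1 (0.29) and Pfkfb4 (0.77) rose. The IL-6 and STAT3 list had 4 of 26 higher and 6 lower (6 and 7 adjusted over the list alone, camera adjusted p = 0.766). Hif1a (-0.31) and Socs3 (-0.37) fell and Ly6c2 (0.24) rose. Stat3 and Cpt1a did not pass (0.17 and -0.02, edgeR adjusted p = 0.0958 and 0.844).

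By edgeR, 2607 of 15018 genes rose and 2638 fell in hypoxia, 5245 in all. The genotypes did not overlap for 32.6% of the tested genes, where chance gives 2.86%. With a fold threshold of 1.2 the count was 1959, and 21 of 35 splits of the libraries called at least as many lists as the real one (8). Socs3, Hif1a, Cd274 and Ly6c2 were the called genes named here that lost their call when 1 library was left out, with a highest edgeR adjusted p = 0.0908 for Socs3 without KO replicate 1, 0.0557 for Hif1a without KO replicate 3, 0.113 for Cd274 without KO replicate 2 and 0.0672 for Ly6c2 without WT replicate 3.

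**Figure D3:**
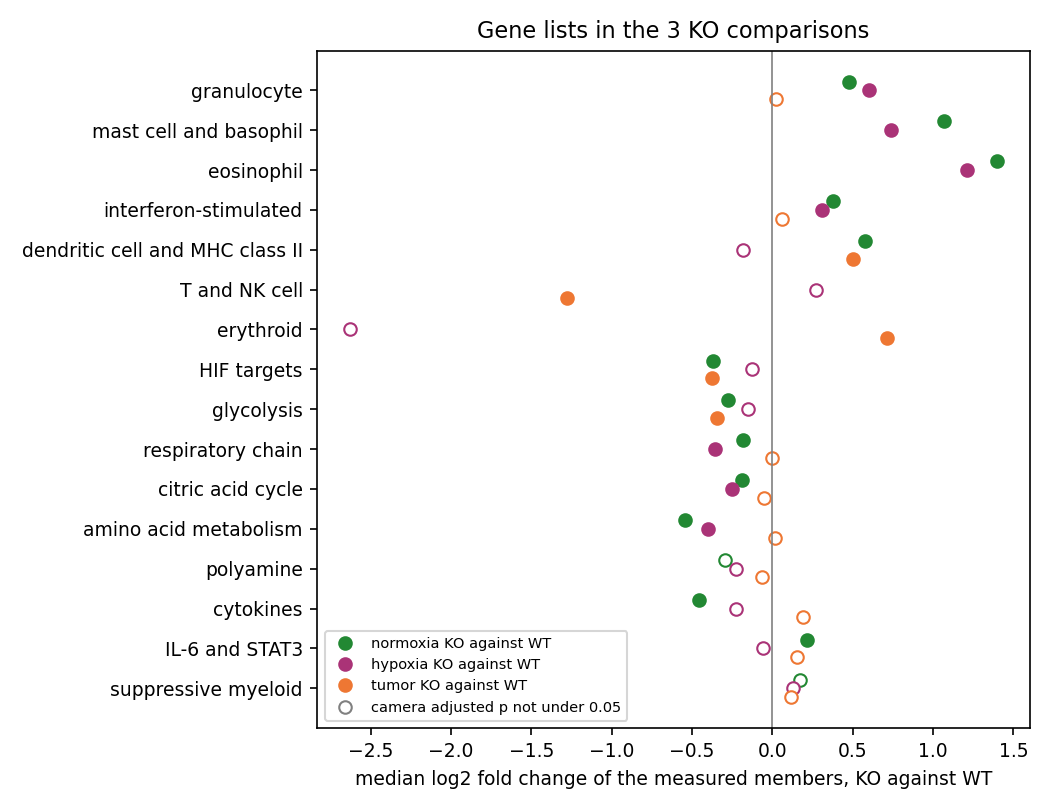
Median log2 fold change of the measured members of each gene list (x axis) in the 3 KO comparisons (colour), by list (y axis), with open points where the camera adjusted p is not under 0.05 at an inter-gene correlation of 0.01. The eosinophil medians are 1.40 in normoxia and 1.21 in hypoxia, and the T and NK cell median in tumor is -1.28; with an estimated correlation 0 lists pass in each comparison.

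In MC38 tumor samples, KO differed from WT in genes of low-oxygen response, glucose use and T cells, which were lower, and in antigen presentation genes, which were higher. None of these lists passed with an estimated correlation, and the T and NK cell list did not pass with fry (adjusted p = 0.188). Arg1 fell from 4640 ± 156 to 3270 ± 281 CPM (SD, n = 3 each, log2 fold change -0.50 ± 0.078 SE) and Slc2a1 from 819 ± 37.5 to 623 ± 13.7 CPM (-0.39 ± 0.067 SE). Gapdh, a glycolytic enzyme gene, fell from 4560 ± 297 to 2760 ± 142 CPM. Ciita rose from 137 ± 14.2 to 215 ± 17.8 CPM, and Cd28, a T cell co-receptor gene, fell from 6.53 ± 1.2 to 1.74 ± 0.503 CPM.

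The largest rises were Ifi202b (log2 fold change 6.51), Eno2 (5.41), Camk2b (5.29), Ppfia4 (5.16), Cnbd2 (4.52) and Cep85 (4.00). The largest falls were Chil1 (-7.73), from 452 ± 57.5 to 2.15 ± 0.989 CPM, Ifi213 (-4.56), Npl (-4.03), Mpeg1 (-3.26), Ifi206 (-3.11) and Ctse (-2.93). Ifi202b, Ifi213 and Ifi206 are similar genes of 1 family that lie within 170 to 175 Mb of chromosome 1, and how their reads were assigned is uncertain. In that window 35 of 83 tested genes were called, against 5.24 by chance, and windows on chromosomes 11, 6 and Y also held more called genes than chance. Without gene families, 13 and 16 called genes were left on chromosomes 11 and 6 and 1 on Y (exact hypergeometric p = 2.88e-06, 9.99e-08 and 0.0623). The window of 120 to 125 Mb on chromosome 6, which holds Eno2 and Slc2a3, had 16 called of 64 tested. Of the genes that changed by at least 2 on the log2 scale, 31% lay in these windows, which held 1.43% of the tested genes. The windows were chosen for their excess of called genes, so part of this follows from the choice.

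**Figure D4:**
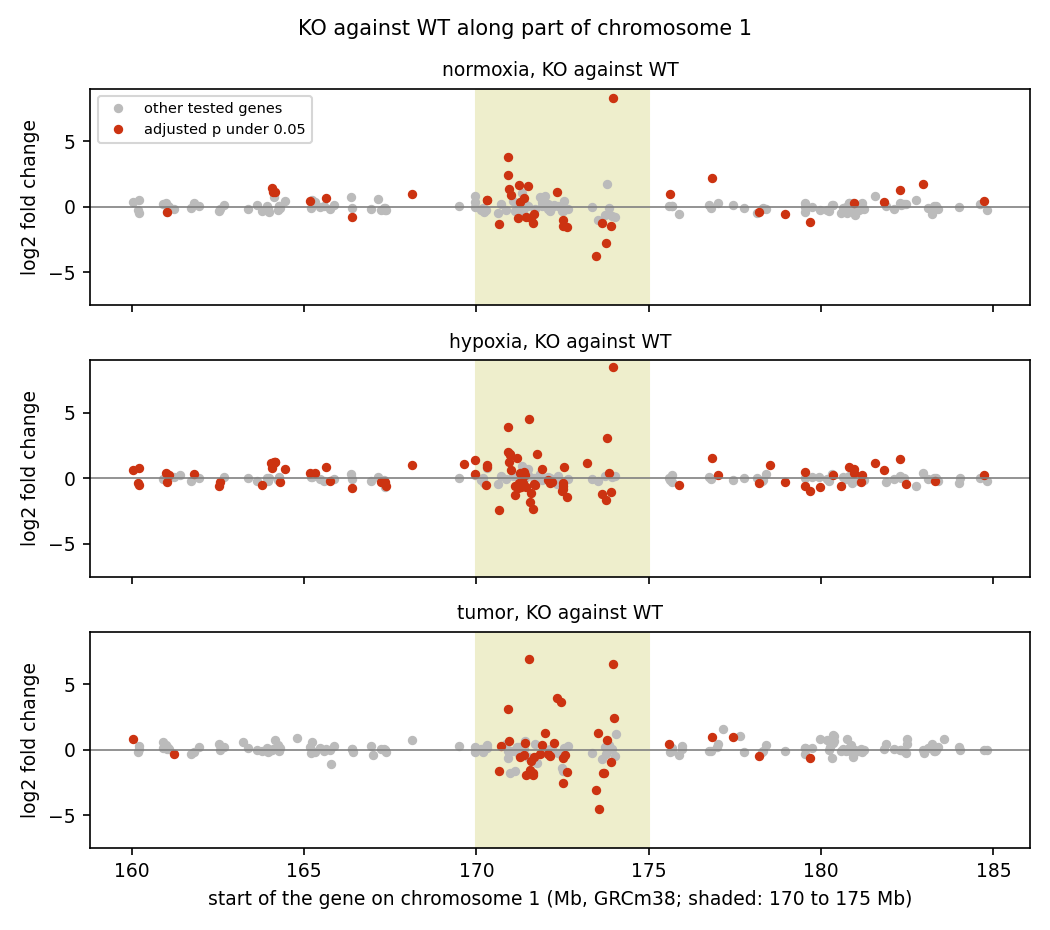
Log2 fold change of KO against WT (y axis) by the start of each tested gene on chromosome 1 (x axis, Mb, GRCm38) in the 3 experiments, with genes called by edgeR in red and the window of 170 to 175 Mb shaded. The window holds 25 of 74, 46 of 81 and 35 of 83 called genes in normoxia, hypoxia and tumor, where chance gives 8.35, 28.3 and 5.24. Without gene families the exact hypergeometric p was 0.0091, 0.0191 and 3.04e-08, and only the last lies below the bound of 9.4e-05.

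HIF targets fell in 14 of 23 cases and rose in 0 (18 and 1 adjusted over the list alone, 9 called without KO replicate 2), with Ero1l at -0.66, Ndrg1 at -0.76, Mxi1 at -0.57 and Pgk1 at -0.43. The camera adjusted p was 2.16e-10, and adjusted p = 0.166 with an estimated correlation. Of 24 glycolysis genes, 13 fell and 1 rose (17 and 3 adjusted over the list alone, 9 called without KO replicate 2), with Gapdh at -0.72, Gpi1 at -0.66 and Slc2a3, a glucose transporter gene, at -1.30, against Eno2 at 5.41. With camera the adjusted p was 1.14e-07, and adjusted p = 0.42 with an estimated correlation. Of the glycolysis genes, Slc2a3, Eno2 and Tpi1 (-0.38) lie in the chromosome 6 window of 120 to 125 Mb, where called genes cluster. Gapdh starts just beyond its edge. Among dendritic cell and MHC class II genes, 10 of 20 rose and 0 fell (13 and 0 adjusted over the list alone, 4 called without WT replicate 2), with Cd209a at 1.38, Flt3 at 1.46 and Cd40 at 0.48. In the camera test the adjusted p was 7.38e-08, and adjusted p = 0.0787 with an estimated correlation.

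T and NK cell genes fell in 9 of 19 cases and rose in 0 (12 and 1 adjusted over the list alone), with a median log2 fold change of -1.28. WT replicate 3 stood apart from WT replicates 1 and 2, with Trac at 12.8 CPM against 5.2 and 6.06, and without it the median was -0.856 (camera adjusted p = 0.000766). Without KO replicate 1 or 2, 2 and 1 genes of the list were called. Foxp3, the regulator of regulatory T cells, was at -1.93, Gzmb at -1.40 and Cd3e at -1.70. Most of these genes were at low levels. In the WT libraries Cd3e was at 2.11, 2.21 and 4.67 CPM and Cd4 at 2.11, 1.6 and 3.12 CPM. Gzmb, the highest of the list, was at 19.6, 19.9 and 36.5 CPM, and the myeloid gene Ly6c2 at 3145, 3048 and 2416 CPM. The number of T cells in the tumors was not measured. Tested with camera, the list had adjusted p = 8.89e-05, and adjusted p = 0.677 with an estimated correlation. Erythroid genes rose in 3 of 5 cases (4 adjusted over the list alone, 1 called without WT replicate 1 or KO replicate 1 or 2), with Hba-a1 at 0.72, Hba-a2 at 0.66 and Hbb-bt at 0.92, while Hbb-bs (0.94) had an edgeR adjusted p = 0.0502. The list had a camera adjusted p = 0.00153, and adjusted p = 0.636 with an estimated correlation. Immediate early genes, which handling of a sample can raise, rose in 5 of 17 cases and fell in 0, the same adjusted over the list alone (1 called without KO replicate 2 and 2 without WT or KO replicate 1), with Egr1 at 0.41, Egr2 at 0.49, Ier2 at 0.31 and Nr4a1 at 0.25. Their camera adjusted p was 0.00214, and adjusted p = 0.487 with an estimated correlation. Fibroblast genes were higher as a list (median log2 fold change 0.401, 9 of 10 above 0), with 1 called higher and 0 lower (3 and 0 adjusted over the list alone), a camera adjusted p = 0.0136, and adjusted p = 0.487 with an estimated correlation. Their list lost its call without KO replicate 1 or 3 (camera adjusted p = 0.0808 and 0.242). Protein genes of the mitochondrial genome, whose share RNA quality can move, were above 0 in 13 of 13 cases (median 0.414) with 0 called by edgeR, also adjusted over the list alone. For that list the camera adjusted p was 0.00449, and adjusted p = 0.728 with an estimated correlation. Mitochondrial genes took 0.1119% of the counts in WT replicate 2 against 0.2119% and 0.211% in the other WT libraries, and without it the median was 0.15 (camera adjusted p = 0.0157).

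Cytokine, suppressive myeloid, polyamine and IL-6 and STAT3 genes did not pass as lists in tumor (camera adjusted p = 0.109, 0.69, 0.349 and 0.13). In the IL-6 and STAT3 list 4 of 27 rose and 3 fell, the same adjusted over the list alone. In the cytokine list 2 of 25 genes rose and 3 fell (6 and 4 adjusted over the list alone), with Ccl5 at 1.35, Il1rn at 0.76, Cxcl3 at -1.04 and Ccl7 at -0.47. In the suppressive myeloid list 2 of 25 rose and 4 fell (6 and 5 adjusted over the list alone), with Ptgs2 at 0.43, Nt5e, the gene of the adenosine-producing CD73, at -1.03, Cd84 at -0.34 and Nos2 at -0.31. Of 21 polyamine genes, Arg2 (0.74) rose and Arg1 fell (1 and 2 adjusted over the list alone), while Odc1 (-0.09), Slc3a2 (-0.22) and Atp13a2 (-0.16) did not pass. Socs3 rose (0.63). Hif1a, Stat3, Cpt1a, Cd274, Ly6c2, Il1b, S100a8 and S100a9 did not pass (0.19, 0.14, 0.08, 0.09, -0.05, 0.54, 0.43 and 0.47).

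By edgeR, 471 of 14370 genes rose and 437 fell in tumor, 908 in all. The genotypes did not overlap for 26.1% of the tested genes, where chance gives 10%. The count was 515 without WT replicate 2, 444 and 455 without KO replicate 1 or 2, 1363 with no filter and 333 with a fold threshold of 1.2, and 3 of the 25 lists passed with fry, while 3 of 10 splits called at least the real 8 lists. Of the 47 called genes named here, 11 lost their call when 1 library was left out, among them Nos2 (edgeR adjusted p = 0.135 without KO replicate 1), Cd3e (0.0909 without KO replicate 2) and Foxp3 (0.0751 without KO replicate 2).

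The KO effects of the 2 culture experiments were correlated across genes, with Pearson's r = 0.729 and Spearman's rho = 0.743 over 13711 genes, which are not independent replicates. Both called 762 genes higher, where independence gives 169, and 436 lower, where it gives 108. Of the 1211 genes called in both, 1198 had the same sign. Tumor effects had r = 0.299 with normoxia (rho = 0.214) and r = 0.276 with hypoxia (rho = 0.191). Of the genes called in both, 144 of 197 and 293 of 405 had the same sign. Among 12461 genes tested in all 3 experiments, 61 rose and 54 fell in each, Slc2a1 and Arg1 among those that fell. The chromosome 1 window of 170 to 175 Mb, where called genes cluster, holds some of them. Ifi202b and Fcrla there were higher and Slamf7, Ly9 and Olfml2b lower. With genes of at least 3 in mean log2 CPM, r with tumor was 0.176 for normoxia and 0.127 for hypoxia.

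The difference between the KO effects was tested to ask which genes differ between KO and WT unlike in the hypoxia and normoxia cultures. These cultures also differ in time and come from separate tables, so a difference cannot be assigned to oxygen. Mid1 had 1.85 ± 0.628 CPM in WT and 1.6 ± 0.854 CPM in KO in normoxia, and 4.85 ± 0.975 and 99.1 ± 25.8 CPM in hypoxia (SD, n = 4 each). Mid1-ps1, in the chromosome Y window, moved with it, at log2 fold changes of -0.15 in normoxia and 4.38 in hypoxia. How reads were divided between Mid1 and Mid1-ps1 is uncertain. The progesterone receptor gene Pgr was at 16.7 ± 4.2 and 17.7 ± 5.99 CPM in normoxia and at 1.2 ± 0.229 and 9.89 ± 2.55 CPM in hypoxia. Ciita rose in KO in normoxia, from 1.47 ± 0.675 to 8.42 ± 2.8 CPM, and was at 22.7 ± 5.74 and 19.8 ± 6.3 CPM in hypoxia. Acod1 fell by 1.67 on the log2 scale in normoxia and by 0.31 in hypoxia.

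The largest positive differences were Mid1 (log2 4.55), Pgr (2.96), Vcam1 (1.76), Perp (1.38) and Acod1 (1.37). The largest negative ones were Ciita (-2.71), H2-Ab1 (-2.45), Plet1 (-2.10), the chemokine gene Ccl17 (-2.03) and Vcan (-1.43). Of 19 dendritic cell and MHC class II genes, 2 differed, both negative (8 negative and 1 positive adjusted over the list alone), and H2-Eb1 (-2.68) and H2-Aa (-2.55) did not pass (edgeR adjusted p = 0.0642 and 0.0682). The list had a camera adjusted p = 6.14e-09, and adjusted p = 0.421 with an estimated correlation and 0.142 with fry, which passed 0 lists where camera passed 11. The 13 genes of the mitochondrial genome all lay below 0 there (median -0.352, 0 called by edgeR, 4 adjusted over the list alone, camera adjusted p = 4.77e-07, and adjusted p = 0.465 with an estimated correlation). Socs3, which rose in normoxia and fell in hypoxia, had a difference of -0.80 with an edgeR adjusted p = 0.0526. For Arg1 the difference was 1.15 ± 0.83 SE and for Odc1 -0.13 ± 0.33 SE, and neither passed (edgeR adjusted p = 0.855 and 0.991).

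By edgeR, 29 of 15293 genes had a positive and 44 a negative difference, 73 in all, or 42 and 42 with library size alone. The count was 195 with DESeq2, and it fell to between 40 and 48 without normoxia WT replicate 2 or 4, normoxia KO replicate 3, hypoxia WT replicate 1, 2 or 3, or hypoxia KO replicate 2 or 4. H2-Ab1, Vcam1 and Vcan lost their call when 1 library was left out, with a highest edgeR adjusted p = 0.118 for H2-Ab1 without normoxia WT replicate 4, 0.0637 for Vcam1 without hypoxia WT replicate 1 and 0.0521 for Vcan without hypoxia KO replicate 2.

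Hypoxia WT and normoxia WT cultures were compared to see what the oxygen condition itself changed. Genes of low-oxygen response and glucose use and of mast cells and eosinophils were higher in hypoxia, and interferon-stimulated genes were lower. Immediate early genes, which handling can raise, and endothelial genes were higher too, and no list passed with an estimated correlation. Slc2a1 rose from 161 ± 16.9 to 361 ± 11.4 CPM and Arg1 from 25.7 ± 17.5 to 164 ± 37.9 CPM (SD, n = 4 each). Epx, an eosinophil granule peroxidase gene, rose from 8.31 ± 2.02 to 830 ± 224 CPM. Vsir fell from 703 ± 87 to 578 ± 48.3 CPM (log2 fold change -0.28 ± 0.094 SE).

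Epx (log2 fold change 6.64) and Ptgs2 (6.31), the cyclooxygenase 2 gene, were among the largest rises, with Hba-a1, Hba-a2 and Hbb-bs. The 4 normoxia WT libraries together held 1 count of Hba-a1, 1 of Hba-a2 and 6 of Hbb-bs, and the hypoxia WT libraries held 3106, 2466 and 2772. The ratios of these levels were 2350 (95% exact interval 421 to 92800), 1860 (334 to 73700) and 349 (160 to 953), for counting error only. The largest falls were Pgr (-3.80), the ceruloplasmin gene Cp (-3.23), Mmp2 (-3.17), Clec4b2 (-2.58) and Oas1g (-2.20).

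Of 22 HIF targets, 19 rose and 1 fell (20 and 1 adjusted over the list alone), with Hilpda at 3.95 and Egln3 at 1.86, and of 23 glycolysis genes 18 rose and 2 fell (19 and 2), with Slc16a3 at 1.49, Pkm at 1.36, Ldha at 1.26 and Pgk1 at 1.26. Camera gave adjusted p = 1.42e-07 for both lists, and adjusted p = 0.231 and 0.161 with an estimated correlation. Interferon-stimulated genes fell in 26 of 29 cases and rose in 2, the same adjusted over the list alone, with Rtp4 at -3.49, Oas1a at -1.55, Ddx58 at -1.24 and Zbp1 at -1.17. Their camera adjusted p was 2.38e-08, and adjusted p = 0.175 with an estimated correlation. Of 9 mast cell and basophil genes 8 rose and 0 fell, and the same was true of 9 eosinophil genes, also adjusted over each list alone. Gata2 (6.06), Cpa3 (5.98), Mcpt8 (5.62), Prss34 (5.55), Prg2 (6.00), Prg3 (5.63) and Ear1 (5.62) are examples. Camera gave adjusted p = 5.56e-08 and 7.37e-06, and adjusted p = 0.161 and 0.175 with an estimated correlation. Immediate early genes rose in 13 of 17 cases and fell in 1, the same adjusted over the list alone (median 1.12), and all 6 endothelial genes rose, also adjusted over the list alone (median 1.36). Camera gave adjusted p = 3.52e-06 and 0.000148, and adjusted p = 0.175 and 0.161 with an estimated correlation. All 5 erythroid genes rose, also adjusted over the list alone, including Hbb-bt (6.22), with a camera adjusted p = 7.32e-05, and adjusted p = 0.175 with an estimated correlation.

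Il1b (3.47), Nos2 (3.54), Cd274 (1.11), Socs3 (0.69) and Stat3 (0.59) rose in hypoxia WT, and Ly6g (-1.45), S100a8 (-1.01), S100a9 (-0.41) and Ly6c2 (-0.27) fell. Hif1a, Cpt1a and Odc1 did not pass (-0.17, 0.18 and 0.21). By edgeR, 3781 of 14545 genes rose and 3973 fell, 7754 in all (2951 and 5535 with library size alone), and the groups did not overlap for 47.6% of the tested genes, where chance gives 2.86%. The 2 groups also differ in culture time and come from separate tables, so oxygen cannot be told apart from these, and 10 of 35 splits called at least the real 14 lists. Vsir lost its call without normoxia WT replicate 3 or hypoxia WT replicate 1, 3 or 4, with edgeR adjusted p up to 0.065, and S100a9 lost its call without normoxia WT replicate 3 or hypoxia WT replicate 2 or 4 (0.0561, 0.052 and 0.0655).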

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

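The counts over other splits of the libraries were planned. The tests of 3 patterns given further down (neighbouring genes, mast cell and eosinophil genes, T cell genes) were chosen only after the result was seen, and after first values were known the test of the main cell type's share was divided by experiment and its bound changed more than once, the test of depth was replaced, the chromosome Y window was given its own test, and tests of lineage and T cell RNA that only repeated the pattern were dropped.

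In 252 groups of 4 libraries (a named gene in 1 genotype of 1 culture experiment), 16 held a library far from the other 3, where chance gives about 1 in 20 groups, or 12.6. Tumor groups of 3 were not tested. Among normoxia WT libraries, Slc7a2 was at 23.7 CPM in replicate 2 (31.3 to 32.8 in the others) and Egln3 at 97.4 CPM in the same replicate (130 to 137). Prss34 was at 5.43 CPM in replicate 3 (4.17 to 4.28) and Cebpd at 92.9 CPM there (67.8 to 70.3), while Kit was at 16.8 CPM in replicate 1 (24.1 to 25.7). Normoxia KO libraries had Nos2 at 0.671 CPM in replicate 2 (2.72 to 3.31) and Oas2 at 32.9 CPM in replicate 1 (25.5 to 26.3). Replicate 4 of the same group had Ifi204 at 6.97 CPM (2.42 to 2.90) and Ass1 at 85.5 CPM (146 to 158). In hypoxia WT libraries, replicate 2 had Olfml2b at 29 CPM (40.4 to 42.5) and Psap at 7630 CPM (5410 to 5730), and replicate 4 had Kit at 29.8 CPM (23.8 to 24.6). In hypoxia KO libraries, replicate 4 had Vsir at 113 CPM (156 to 163) and Psat1 at 93.8 CPM (66.7 to 69.3). Replicate 3 there had Gata1 at 5.92 CPM (9.11 to 9.26) and Nnt at 0.229 CPM (0.462 to 0.488).

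The KO effect differed between hypoxia and normoxia in edgeR's interaction test for 10 named genes (hypoxia minus normoxia, log2). Mid1 (4.55), Pgr (2.96), Vcam1 (1.76), Perp (1.38) and Acod1 (1.37) had a positive difference. Ciita (-2.71), H2-Ab1 (-2.45), Plet1 (-2.10), Ccl17 (-2.03) and Vcan (-1.43) had a negative one.

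Other splits of the libraries show how often another division reaches each count. In the KO experiments and the oxygen comparison, each other split mixes the groups compared, so a real difference widens the spread within its groups. Few called genes in those splits are thus partly built in, and do not exclude chance by themselves. In normoxia, 1 of 35 splits, the real one, gave 1577 genes and the highest of the others 0. That is a share of 0.0286, under 0.05 and the smallest that 35 splits allow. For the lists 1 of 35 gave 16 and the highest other 15, a margin of 1 list, and the real count was 13 to 15 without 1 library, so this does not settle whether chance can be excluded. In hypoxia, 1 of 35 gave 5245 genes and the highest other 1, the same smallest share. For the hypoxia lists chance is not excluded: 21 of 35 splits gave at least the real 8, with a highest other count of 14. In the oxygen comparison 1 of 35 splits gave 7754 genes and the highest other 0, again the smallest share. There 10 of 35 gave at least the real 14 lists, with a highest other count of 16, so chance is not excluded for the lists. The tumor experiment has 10 splits, too few for a share under 0.05: 1 gave the real 908 genes with a highest other of 0, and 3 gave at least the real 8 lists with a highest other of 9. For the difference of effects, 5 of 100 splits drawn gave at least the real 73 genes, and the highest other gave 2786. That number is many times the real one and points to a structure of the samples: the 4 other draws keep the genotypes apart in 1 oxygen condition and mix them in the other, so the shared KO effect enters the difference. The 94 draws that mix them in both gave at most 1 gene, and the share of 5 in 100 does not settle whether chance can be excluded.

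Called genes of the tumor comparison lie close together on a few chromosomes, with 35 of 83 tested genes called at 170 to 175 Mb of chromosome 1. Reads shared between paralogs are argued against as the whole cause in that window. There 15 genes stayed called without its gene families, where chance gives 2.74. In the chromosome Y window this test cannot decide, as 1 gene is left there. Of 6 genes fixed as a check of sex (Xist, Tsix, Ddx3y, Uty, Kdm5d and Eif2s3y), 1 was measured in tumor. Most Y-linked genes checked thus had too few counts to test, and reads in the chromosome Y window may come from paralogs elsewhere. These clusters lie on other chromosomes than Vsir, so DNA around the targeted allele does not hold them. Whether such DNA changed genes near Vsir stays open. The window of Vsir held 4 called of 39 tested genes (chance 2.46, exact hypergeometric p = 0.23). Vsir lies near the edge of that window, so it covers little of the DNA on 1 side. Oit3, beyond that edge, fell in all 3 experiments (-1.36, -0.87 and -1.73). Chromosome segments of another origin in the KO animals are a candidate explanation that may account for the clusters. Without the families the exact hypergeometric p was 3.04e-08, below the bound of 9.4e-05 over 533 windows. That p restates the clustering and does not tell such segments from other causes of it. Regulation shared by neighbouring genes and a response to VISTA loss stay open and were not tested.

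Mast cell, basophil and eosinophil genes were higher in KO cultures. With library size alone, the largest of the 4 list p-values was a camera adjusted p of 0.000207. Camera sets a list against the other genes, and scaling shifts all genes of a library alike. The test could therefore hardly come out otherwise, and scaling stays open. A lower share of the main cell type would raise the markers of every other type alike. In hypoxia the erythroid median was -2.63 and the fibroblast median 0.31, a gap of 2.94 beyond the larger quartile range of 2.35. The erythroid median rests on 4 globin genes that fell, while 3 of 7 T and NK cell genes and 3 of 6 fibroblast genes rose. The erythroid genes Klf1 (0.32) and Epor (0.66) lay above 0 without a call. The B cell and dendritic cell medians were -0.142 and -0.181. A gap that rests on globin genes does not decide the question, so a lower share stays open in hypoxia. In normoxia it stays open too, since only 2 such lists had 5 measured members, with a gap of 0.674. More RNA of these lineages and a response of the genes themselves to VISTA loss stay open too and were not tested.

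T cell genes were lower in KO tumor samples. The lower depth of the KO libraries is argued against, since 10000 sets of other genes of the same abundance had a typical median log2 fold change of 0.0885 (95% of sets -0.106 to 0.337) against -1.28 for the list. A lower share of all cells other than the main type is argued against for fibroblasts and erythroid cells alone, with medians of 0.401 and 0.715. The fibroblast list lost its call without KO replicate 1 or 3. Shorter lists went both ways. B cell and eosinophil genes had medians of -0.0916 and -0.461 (4 and 3 measured), and mast cell and epithelial genes 0.735 and 0.84 (4 measured each). Less T cell RNA in KO samples, how the samples were taken (the labels name no sort, though the name of the count table says MDSC) and a response to VISTA loss stay open and were not tested.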

How the results depend on the processing

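All alternatives were planned except those that leave out chromosome windows or normoxia KO replicate 4 with WT replicate 3, the library left out for the correlations, and the list test of the difference, which were chosen after the data had been seen. Under the alternatives run, 0 described lists or correlations changed sign. For named genes, 0 values changed sign where the main or the alternative fit called the gene. The balance of rises and falls in normoxia turned with library size alone. Of 4622 alternative values for 260 named-gene results, 4334 kept direction and side of the threshold, 216 lost the call and 45 gained it. The other 27 changed sign with no call in the main or the alternative fit. For 37 list results, 327 of 379 values kept theirs, 35 lost the call and 17 gained it. The cause of a change was not tested unless it is stated.

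Gene counts moved by more than 1.5 times with DESeq2 in normoxia (2388 against 1577) and for the difference of effects (195 against 73). With a fold threshold of 1.2, which by construction calls fewer, they were 416 in normoxia, 1959 in hypoxia and 333 in tumor. The tumor count was 1363 with no filter. With the replicate number as a block, it was 2266 in tumor and 40 for the difference. Replicate numbers were not shown to pair the samples: correlations of KO with WT libraries of the same number ran from -0.0571 to 0.372 in normoxia, -0.159 to 0.0189 in hypoxia and 0.0797 to 0.218 in tumor. KO libraries correlated best with the WT library of their own number in 2 of 4 cases in normoxia, 0 of 4 in hypoxia and 3 of 3 in tumor, a hint from the data and not from the design. Without normoxia KO replicate 4 and WT replicate 3 the normoxia count was 2881. Leaving out 1 library gave 469 to 2233 genes in normoxia, 3859 to 5703 in hypoxia, 444 to 1072 in tumor, 40 to 100 for the difference and 6817 to 8371 for oxygen. Libraries that lowered the count most are named beside the normoxia, tumor and difference counts in the results. With library size alone the share of called genes that were higher was 43.3% in normoxia (63.1% with TMM), 50% for the difference (39.7%) and 34.8% for oxygen (48.8%), where the median of all genes moved from -0.0319 to -0.155.

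With a correlation estimated per list, 0 lists passed in normoxia, hypoxia, tumor, the difference and the oxygen comparison, against 16, 8, 8, 11 and 14. Fry passed 14, 11, 3, 0 and 18. Leaving out 1 library gave 13 to 15 lists in normoxia, 9 to 12 in hypoxia and 7 to 10 in tumor. Correlations between normoxia and hypoxia were 0.79 over genes called in either and 0.815 at a mean log2 CPM of at least 3. The same choices gave 0.369 and 0.176 for normoxia with tumor and 0.321 and 0.127 for hypoxia with tumor. Without the chromosome windows these last pairs had 0.246 and 0.189. Leaving out 1 library gave 0.695 to 0.743, 0.245 to 0.313 and 0.234 to 0.282. Of simulated 1.5-fold changes in genes of at least 3 in mean log2 CPM, 42.4% were found for the difference of effects. Its libraries gave 74.2% and 95.5% in normoxia and hypoxia alone.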

Other observations

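The list tests for the difference of effects in this part were chosen only after the data had been seen.

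Fatty acid oxidation genes fell in 8 of 20 cases and rose in 1 in hypoxia KO cultures (9 and 1 adjusted over the list alone), with a camera adjusted p = 0.0265, and adjusted p = 0.389 with an estimated correlation. In normoxia 4 of 20 fell and 0 rose (7 and 0 adjusted over the list alone, camera adjusted p = 0.0123, and adjusted p = 0.371 with an estimated correlation). There 0 were called without WT replicate 1 or 4 or KO replicate 3, and 6 without KO replicate 2. In hypoxia KO 0 of the 13 genes of the mitochondrial genome were called by edgeR and the list did not pass (camera adjusted p = 0.982).

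Cell cycle genes were lower in hypoxia WT than in normoxia WT cultures in 27 of 30 cases (28 adjusted over the list alone), with a camera adjusted p = 7.37e-06, and adjusted p = 0.63 with an estimated correlation. Nuclear-encoded respiratory chain genes fell there in 41 of 76 cases and rose in 3 (the same adjusted over the list alone, camera adjusted p = 1.52e-05, and adjusted p = 0.665 with an estimated correlation). In the difference of KO effects the erythroid list had a camera adjusted p = 0.00163, and adjusted p = 0.421 with an estimated correlation and 0.107 with fry. For 6 erythroid genes in that test, 0 were called by edgeR over all genes.

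In normoxia KO cultures, nuclear-encoded respiratory chain genes fell in 5 of 76 cases and citric acid cycle genes in 2 of 23, and 0 of either rose (0 and 4 fell adjusted over each list alone). Their camera adjusted p was 1.28e-06 and 7.58e-05, and adjusted p = 0.456 and 0.371 with an estimated correlation. Without WT replicate 1 both lists had 0 called genes, and without KO replicate 2 they had 14 and 4. The respiratory chain list also had 0 without WT replicate 2 or 4 or KO replicate 3. Of 23 glycolysis genes, 7 fell and 3 rose there (10 and 3 adjusted over the list alone, camera adjusted p = 0.0368, and adjusted p = 0.456 with an estimated correlation). That list lost its call without WT replicate 3 (camera adjusted p = 0.152), and without WT replicate 1 it had 4 called genes. In hypoxia KO cultures the glycolysis list did not pass (camera adjusted p = 0.528), and its median log2 fold change of -0.149 and mean of 0.198 differed in sign. The suppressive myeloid list in normoxia, with 2 of 23 genes higher and 5 lower, did not pass either (camera adjusted p = 0.519), and its median was 0.17 and its mean -0.10.

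A further 4 lists were higher in hypoxia WT than in normoxia WT cultures by camera. Cytokine genes rose in 17 of 24 cases and fell in 4, suppressive myeloid genes in 14 and 7 of 23, monocyte and macrophage genes in 12 and 4 of 23, and dendritic cell and MHC class II genes in 14 and 1 of 19 (18 and 4 for cytokines adjusted over the list alone, the same for the others). The camera adjusted p was 4.06e-06, 0.0116, 0.00483 and 7.46e-05, and adjusted p = 0.161, 0.529, 0.673 and 0.386 with an estimated correlation.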
